A study of Nasonia vitripennis with 7 samples.

How the data were processed

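The data were DAP-seq libraries of genomic DNA from whole bodies of the wasp Nasonia vitripennis, strain AsymCX. Per the labels' protocols, purified DNA was broken by ultrasound to a target size of 150 bases, joined to adaptors, enriched with DSX or with luciferase on a matrix, amplified by PCR with an index for each sample, and sequenced as pairs of 150 bases. Samples were grouped by the protein named in their labels, which gave 4 DSX and 3 luciferase libraries. The names of the DSX libraries hold the letter F in 2 libraries and M in the other 2, which the labels do not explain. The 4 were kept as 1 group. Because the peak list does not keep libraries apart, any difference between the F and M libraries is not analysed here, and a peak need not be present in both.

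The submitters' processing notes name Bowtie2 2.3.5.1, MACS2 2.2.5, bedtools 2.28.0 and cutadapt, without settings. The peak list gives each peak as a single summit base with the −log10 of a q or p that the authors computed for DSX against luciferase before they deposited it, with MACS2 per the submitters' processing notes. These values are all above 2, and the list does not say which of q and p they are. MACS2 writes −log10 of q there by default. The table of sites gives, per the file headers, a match score, a p-value and a q-value for each match to a 12-base motif. Per the file's footer, FIMO 5.1.0 made this table with a motif that MEME had found in sequences under the peaks, and its name for the peak set reads as all positive peaks together. Libraries were thus not kept apart in either file, no column held values of a single sample, and neither replicate spread nor sequencing depth could be had. How reads from repeated sequence were placed is not given in the sources used here, and neither is the genome build.

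Each match was given to the nearest summit on its scaffold. Matches on opposite strands over the same core were joined to 1 distinct site, read on the strand with the better score. The planned overlap of peaks and sites by 1 base could not serve as the main measure, because the listed peaks are single bases; its value, with the summit base inside the site, is given beside the main one. The length searched per peak, a mean of 135 bases, was worked out from the authors' p-value and q-value of the last match, on the assumption that the q-values count all positions searched. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Strength was compared between sets of peaks on ranks with 100000 permutations, and differences of medians have bootstrap intervals from 10000 resamples. All tests were two-sided. Values called adjusted were adjusted by Benjamini-Hochberg within each family of tests, and p-values without that word are unadjusted.

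The effect of bases on strength was estimated with all testable positions in 1 model of ranks, with permuted residuals. It was tested on simulated data for the 811 peaks with 1 site: the planted position was found in 20 of 20 sets, with 2 calls among 140 unplanted positions, against 29 of 140 when positions were tested singly. In 20 simulated sets of 952 uniform offsets 0 were called, and 20 of 20 centred sets were called. For the 38 scaffolds, 72 of 100 raised scaffolds and 0 of 660 others were called higher. The peaks of these sets were drawn independently, while the real summits were clustered, so false calls in the real list may be more frequent. The correlation test called 1 of 20 sets without a relation and 20 of 20 with one. Each kind of planted effect had a fixed size, so these rates do not hold for smaller effects. The planted rise in strength was larger than any ratio of medians by base in the real list. The work used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

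Groups, the tests of the planned results and the core sequence were chosen before the data were examined. The tests against control windows, by gene feature, by chromosome and over gene lists were left out, because they need a genome on these scaffolds; none of the scaffold names matched a sequence name in the gene table used here, which belongs to another set of coordinates. For the same reason the planned rule for named genes was applied to peaks: the 15 strongest peaks and the 10 peaks with the most sites, ties by the better site score, are named by position. Ties that remained were ordered by strength. The position test used a common span for all peaks in place of each peak's own width. Comparisons of strength between sets of peaks, the tests of summit spacing, of bases and of scaffold extent, and the relations of strength with score and with distance were chosen after the data were seen. The alternatives tried were stricter sets of peaks and sites, other spans around the summit, other forms of the core, merged peaks and other sets of scaffolds.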

Results

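The parasitoid wasp Nasonia vitripennis carries doublesex, a gene whose protein (DSX) is a DM-domain transcription factor at the end of the insect sex determination cascade. The study asked where in the wasp genome this protein binds, and which sequence it binds there. The method was DAP-seq, in which a protein made in vitro is fixed to a matrix and used to pull its target fragments out of a library of naked genomic DNA. Chromatin and the other proteins bound to DNA in cells were therefore removed, and binding in living cells was not measured. The DNA came from whole bodies of the AsymCX strain. DSX enriched 4 libraries, and luciferase, an enzyme chosen as a control that does not interact with DNA, enriched 3 libraries.

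The values analysed were 1 list of peaks for the whole series and 1 table of binding sites found in those peaks. Peak strength below is the authors' own value, the −log10 of the q (or p) of each peak against the luciferase control; the list does not say which of the 2 it is. No value of a single library was analysed here, so the depth of each library is unknown and no spread between replicates could be computed. All tests below treat peaks, sites or scaffolds as the units, and these are not biological replicates. Positions are given on RefSeq scaffolds, counted from 1, and the genome build was not given in the sources used here.

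The DSX libraries gave 2307 peaks over the luciferase control, on 81 scaffolds. Their strength had a median of 5.73, with quartiles of 3.46 and 10.4 and a range from 2.01 to 169. Of them, 610 peaks (26.4%) had a strength over 10, and 20 peaks had a strength over 50. Neighbouring summits lay a median of 66.6 kb apart, and the closest pair lay 224 bases apart. Summits lay closer together than 10000 random placements on the same scaffolds gave: 148 neighbouring pairs lay under 5 kb apart, against a mean of 105 and a 95% range of 86 to 125 in the random sets (two-sided permutation p = 0.0002, the smallest these placements can give; adjusted p = 0.000267 over 4 distances). The number observed was 1.40 times the random mean at 5 kb and 1.12 times at 50 kb, where 944 pairs stood against a mean of 844. The counts include peaks in the runs and recurring copies of 1 sequence described below, and were not repeated without them.

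The strongest peaks stood on several different scaffolds, and most of the first 15 held a listed DSX site within 15 bases of the summit. The strongest of all had its summit at position 5110392 of NW_022279649.1 (strength 169, 4 distinct sites), followed by position 2707972 of NW_022279651.1 (strength 168, 4 sites). Both carried the 12-base site ATACAATGTTTC with its centre 3 bases before the summit, at 5110384 to 5110395 and at 2707964 to 2707975. Position 1019681 of NW_022279652.1 (strength 144) held ATACATTGTATT at 1019673 to 1019684. Position 3357324 of NW_022279591.1 (strength 131) and position 464900 of NW_022279632.1 (strength 112) both held ATACATTGTTTC, the sequence with the highest score in the table (18.45), again with its centre 3 bases before the summit. Position 349719 of NW_022279654.1 (strength 119) held a much weaker match, CAACTTTGTTGC (score 9.70), 14 bases after the summit.

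Further down the 15 strongest peaks, position 7823341 of NW_022279606.1 (strength 77.0) held AAACATTGTTTC, and position 7100428 of NW_022279592.1 (strength 75.6) held 4 sites. A pair of summits on NW_022279624.1, at 1234741 (strength 74.5) and 1233934 (strength 69.96), held copies of ATACATTGTATG, and position 9007738 of NW_022279606.1 (strength 63.9) held 3 sites. The remaining 4 of the 15 had no listed site: position 304305 of NW_022279587.1 (strength 77.7), position 1245377 of NW_022279629.1 (strength 71.1), position 1322591 of NW_022279625.1 (strength 65.5) and position 693647 of NW_022279631.1 (strength 64.6).

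A DSX site was listed in a minority of the peaks. Of the 2307 peaks, 874 (37.9%, exact 95% binomial interval 35.9 to 39.9) held at least 1 site, and 1433 held none. The authors' table listed 1485 matches of 12 bases with 319 different sequences, with scores from 9.47 to 18.45 and q from 0.00206 to 0.0384. The core of the site is close to a palindrome, so that 533 of the places were listed on both strands, and the matches came from 952 distinct sites. Of the peaks with a site, 811 held 1, 54 held 2 and 9 held 3 or more. The motif was found in these same peaks by the authors, so the share is not independent evidence that DSX binds it. The interval covers counting error only. Where the summit base itself had to lie inside the site, the share was 15.3%.

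The share with a site rose with peak strength over the weaker part of the list and then levelled off. It was 14.3% (10.04 to 19.5) in decile 1, the weakest, 29.9% (24.0 to 36.2) in decile 4, 47.6% (41.0 to 54.3) in decile 5 and 54.1% (47.5 to 60.7) in decile 9. In decile 10, the strongest, it was 46.8% (40.2 to 53.4), and its interval overlapped that of decile 9. Peaks with a site had a median strength of 7.51 and peaks without one 4.52, a difference of 2.99 (bootstrap 95% interval 2.52 to 3.54; two-sided permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 1.25e-05 over 5 comparisons of strength). The difference was 3.89 (3.21 to 4.28) on the 11 scaffolds with an extent of 7 Mb or more and 2.13 (0.876 to 2.92) on the 27 shorter scaffolds with at least 20 peaks.

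**Figure D1:**
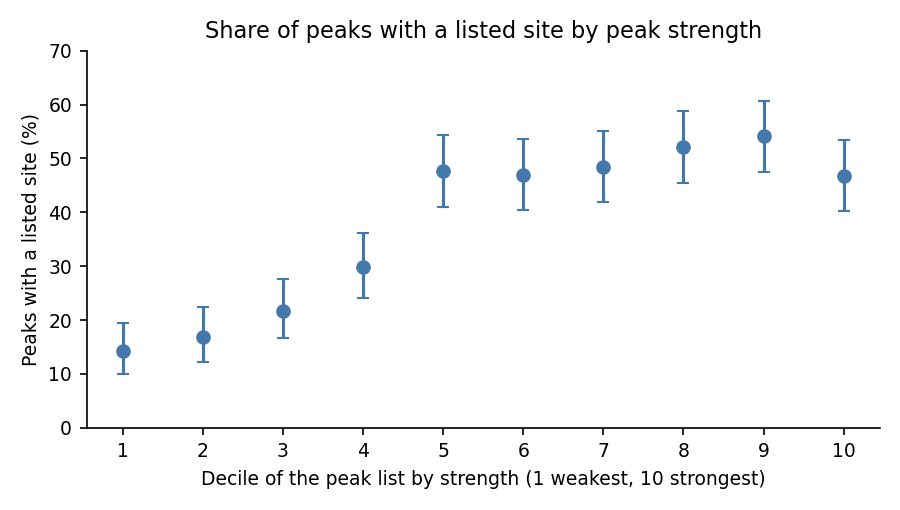
Share of peaks with a listed DSX site (vertical axis, percent) in each decile of the 2307 peaks ranked by strength (horizontal axis, weakest to strongest), with exact 95% binomial intervals as bars. The share was 14.3% in the weakest decile and 46.8% in the strongest.

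The listed sites were built around ACAATGT, the core known for doublesex and related DM-domain proteins. On 1 strand or the other it was present in 802 of the 952 distinct sites (84.2%, exact 95% interval 81.8 to 86.5). The form ACAAAGT, read on the other strand as ACTTTGT, made up 130 sites (13.7%, 11.5 to 16.0), and ACATAGT made up 14 sites (1.47%, 0.806 to 2.46). The degenerate core ACWAWGT, where W is A or T, took in 946 sites (99.4%). Sites with the exact core lay in 748 peaks, which is 32.4% of the list (30.5 to 34.4). A core outside the listed sites was not searched for, and no control windows were drawn, so this share has no background beside it.

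Outside the core the sites were less fixed. Positions are counted from 1 at the left end of the 12 bases, on the strand with the better score. Of the distinct sites, 65.8% had A at the first position and 78.7% had T at the second, while the last position had C in 47.8%, T in 19.9%, A in 17.6% and G in 14.7%. The commonest sequence was ATACATTGTTTC, with 55 distinct sites (5.78%), followed by ATACAATGTTTC with 42 (4.41%). Choosing the better-scoring strand draws these frequencies towards the authors' motif.

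**Figure D2:**
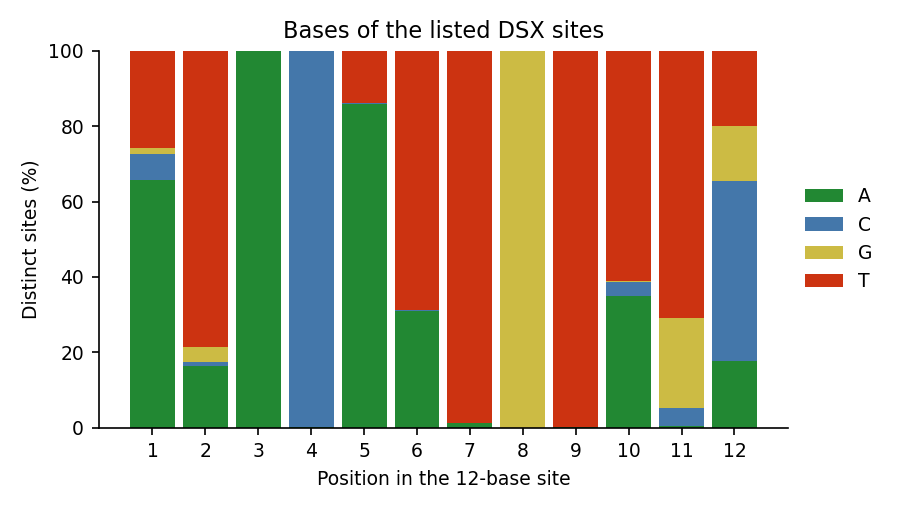
Bases at each position (horizontal axis) of the 952 distinct DSX sites, as a percentage of the sites (vertical axis), with each site read on its better-scoring strand. Position 8 was G in 100% of sites, and the last position was C in 47.8%.

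The sites were gathered at the peak summits. The median distance from the middle of the core to the summit was 12 bases (quartiles 4 and 36), 449 sites (47.2%) lay within 10 bases and 913 (95.9%) within 100 bases. They fell evenly on both sides, 451 before the summit and 459 after it, with 42 on it. Peak widths were not used here, so sites were compared with uniform placement within 61 bases on each side of the summit. This span holds about the mean number of positions searched per peak, 124, as worked out from the authors' q-values. The 850 sites in that span lay a mean of 16.3 ± 16.3 bases (SD) from the summit, against 30.7 for uniform placement (two-sided permutation p = 2e-05, the smallest that the test can give). Peaks of unequal width alone would pull the sites of a pooled list towards the summit over such a span. Within 25 bases, a span narrower than the fragments the peaks were made from, the mean of 618 sites was 7.50 against 12.7 (p = 2e-05 in the same permutation test, again its smallest).

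**Figure D3:**
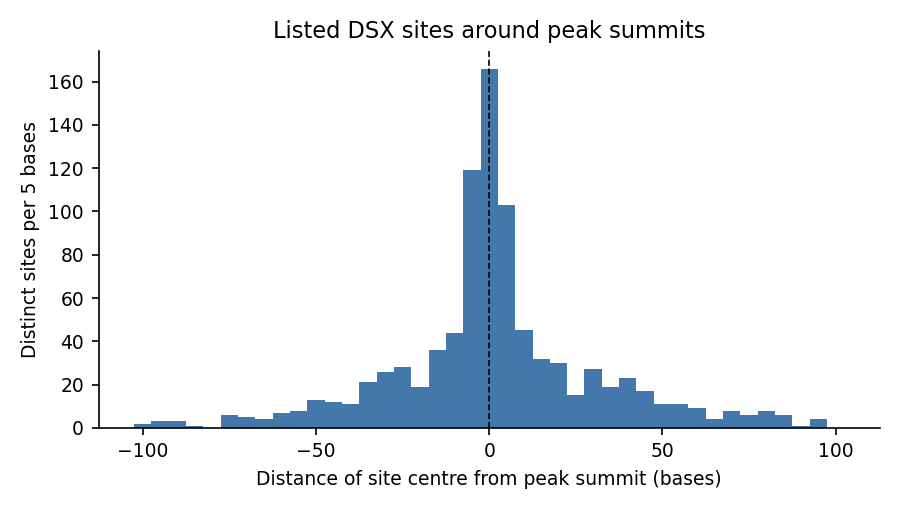
Number of distinct DSX sites per 5 bases (vertical axis) by the distance of the core's middle from the nearest peak summit (horizontal axis, bases), for the 913 sites within 100 bases; the dashed line marks the summit. Sites within 10 bases of the summit made up 47.2% of all 952.

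Stronger peaks held more sites and better sites. Across the 2307 peaks, strength and the number of distinct sites had a Spearman's rho of 0.287 and a Pearson's r of 0.264 (permutation p = 1e-05 for both, the smallest possible; adjusted p = 1e-05 for rho and 1.5e-05 for r, over 3 relations). Without the 2 peaks farthest from the median number of sites, r was 0.241. Among the peaks with at least 1 site, rho was 0.175. Peaks with 2 or more sites had a median strength of 12.5, against 7.19 for peaks with 1 site (difference 5.28, bootstrap 95% interval 2.29 to 7.54; permutation p = 1e-05, adjusted p = 1.25e-05). Without 9 peaks that held a recurring pair of sites with centres 11 bases apart, the difference was 3.18 (1.64 to 5.90, permutation p = 0.00025). Among the 874 peaks with a site, the best score and strength had a rho of 0.353 and an r of 0.222 (adjusted permutation p = 1e-05 and 1.5e-05), and r was 0.222 again without the 2 peaks farthest from the median score. In the 811 peaks with 1 site, the stronger peaks had their site closer to the summit (rho = -0.280, r = -0.178; adjusted permutation p = 1e-05 and 4e-05; r = -0.177 without the 2 farthest). These relations are across peaks, which are not independent replicates. Peak widths were not used here, so any longer search under stronger peaks could not be allowed for. The score measures likeness to a motif that the authors found in these same peaks.

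The peak with the most distinct sites, at position 374455 of NW_022279638.1, held 5 sites but had a strength of only 8.45. All 5 were the same sequence, ATACTTTGTACG, a weak match with a score of 9.53, with their centres within 0.168 kb. Among the 10 peaks with the most sites, 4 others held 4 sites each. They had their summits at 5110392 of NW_022279649.1, 2707972 of NW_022279651.1, 7100428 of NW_022279592.1 and 18874227 of NW_022279606.1, the last with a strength of 56.9. Peaks with 3 sites had their summits at 9007738 (strength 63.9) and 9008433 (strength 41.4) of NW_022279606.1, at 15533406 of NW_022279592.1 (strength 9.62) and at 11822749 of NW_022279611.1 (strength 17.8). The 4 peaks with 4 sites and the peaks with 3 sites on NW_022279606.1 all held the recurring pair of sites. The last of the 10, at 5555770 of NW_022279634.1 (strength 12.9), held 2 sites. A peak on NW_022279606.1, with a site centred at 8792061, tied with it in number of sites and best score (17.6), and strength decided the order.

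The spread of the peaks over the genome was uneven. Chromosomes were not used here, so scaffolds took their place, with the largest summit position as the extent of each. Among the 38 scaffolds with at least 20 peaks, 14 departed from their share of the 1998 peaks by extent (exact binomial test, two-sided, Benjamini-Hochberg adjusted p under 0.05): 8 held more and 6 held fewer. In the stronger part of the list, over scaffolds with at least 10 of its peaks, 21 departed. A short scaffold reaches 20 peaks only where it is dense, so the shorter scaffolds here are not a fair sample of their size. Density ran from 4.88 peaks per Mb on NW_022279623.1 (21 peaks where 36.4 were expected, adjusted exact binomial p = 0.0231) to 16.8 per Mb on NW_022279654.1 (31 peaks where 15.6 were expected, adjusted exact binomial p = 0.00313). The longest scaffold, NW_022279642.1, had 171 peaks where 206 were expected (adjusted exact binomial p = 0.0244). Peaks with and without a listed site were spread differently. Those with a site departed from expectation on 1 scaffold, NW_022279624.1 (24 where 10.4 were expected, adjusted exact binomial p = 0.00791). That call rested on a run of 11 sites of 1 sequence, ATACATTGTATG, in 10 peaks between 1233919 and 1259218. Without the 3 runs of 5 or more neighbouring sites of 1 sequence in the list, the scaffold held 14 peaks with a site where 10.1 were expected (adjusted exact binomial p = 0.600), and 0 scaffolds departed. Over all peaks, the excess on this scaffold (37 where 25.9 were expected, adjusted exact binomial p = 0.0872) and on NW_022279591.1 (54 where 41.9 were expected, adjusted exact binomial p = 0.114) was lost as well, which left 12 scaffolds called, 6 with more peaks and 6 with fewer. Peaks without a site, which the runs by definition do not include, departed from expectation on 27 scaffolds, with more peaks on 17 and fewer on 10. The median over the scaffolds was 3.24 peaks with a site per Mb (range 1.03 to 7.78) and 7.91 without one (1.63 to 10.8).

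**Figure D4:**
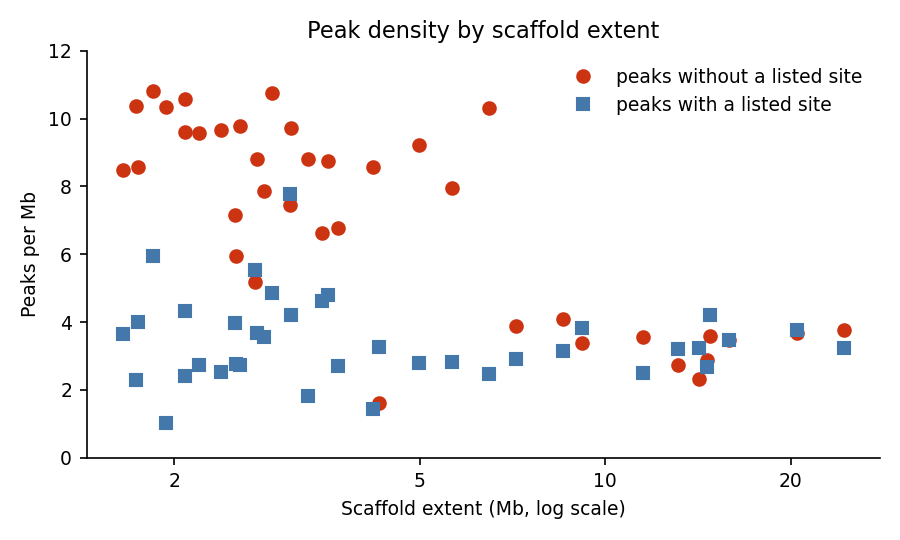
Peaks per Mb (vertical axis) on each of the 38 scaffolds with at least 20 peaks, by scaffold extent (horizontal axis, Mb, log scale), for peaks with a listed site (squares) and without one (circles). Without a site the median was 7.91 per Mb, and with a site 3.24.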

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

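The settings with sites within 25 or 100 bases of the summit, listed matches on both strands, single-site peaks, peaks without the 11-base pairs, the runs of 1 sequence, the strongest decile or short scaffolds, corrected extents, scaffolds chosen by extent, other minimum numbers of peaks per scaffold, and other base tests were chosen after the data were seen. Of the 37 alternatives, 30 left the result on the same side of its threshold, or within its interval or 1.5 times its count. The stronger part of the list held 1153 peaks, by construction. The share of peaks with a listed site was 49.7% in that stronger part, 19.9% with the better-scoring sites only, and 15.3% under the planned overlap, with the summit base inside the site. The share of peaks with the core was 37.7% with the degenerate core and 9.10% with the long consensus, which could be read only at sites listed on both strands. The rise follows from the wider definition. The fall follows in part from the narrower definition and in part from the sites that could not be read. Of the 533 sites listed on both strands, 217 (40.7%) fitted the long consensus. In the stronger part of the list, a change in the peaks and not in the definition, the share with the exact core was 44.1%. Bases called with strength numbered 6 in the joint model and 4 with each position tested singly. No paired analysis was possible because no value of a single library was analysed here. The requirement that a whole site lie inside the peak, bins of peak width, GC-matched windows, shuffled sequences, and the alternatives for gene features, gene lists and peaks per gene were not run, for want of peak widths or a genome. Depth is unknown, so how many sites a deeper set of libraries would add is unknown too.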

Other observations

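The patterns in this part were found in the data, and all of its tests were chosen after that. For the tests of strong peaks, of site scores and of scaffolds chosen by extent, the bounds were set before their own values were computed; the intervals of the first 2 were added later.

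Bases both inside the core (positions 3 to 9 of the site) and outside it went with peak strength. The motif was found in these same peaks, and only matches that passed a threshold were listed. The relations with bases are thus not independent of the relation of score and strength given above. In the 811 peaks with 1 site, C at the last position of the site went with a median strength of 8.38, against 6.36 for other bases (400 and 411 peaks). In a joint model of 8 positions on the ranks of strength, this C went with a rank higher by 98.1 ± 17.5 (SE; adjusted permutation p = 8e-05). A at the first position went with a rank higher by 75.1 ± 16.7 (adjusted permutation p = 8e-05), T at the second by 82.2 ± 20.1 (adjusted permutation p = 0.000107) and A at the fifth, inside the core, by 92.2 ± 23.5 (adjusted permutation p = 0.00028). Inside the core, T at position 6 (adjusted permutation p = 0.0243) and at position 7, where only 10 peaks had another base (adjusted permutation p = 0.0084), also passed, but neither did with each position tested singly. In the exact core, A and T at position 6 are the same core read on opposite strands. At those sites the base at position 6 thus shows which strand scored better, not a different core. T at position 5 and A at position 7 mostly mark the same other cores, ACAAAGT and ACATAGT, read on opposite strands. The calls at positions 5 and 7 are thus not separate effects. In the 687 peaks with the exact core the median strength was 7.51, against 5.86 in the 124 with another core (adjusted permutation p = 0.00015). Positions 10 and 11, outside the core, did not pass (adjusted permutation p = 0.943 and 0.935). Peaks in the runs of 1 sequence were counted as separate cases, and the model was not repeated without them. Peaks whose site was listed on both strands had a median strength of 8.22, against 6.12 for 1 strand (adjusted permutation p = 1.25e-05). A site was listed on both strands only where both readings passed the match threshold, so this split is tied to the score.

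Peaks without a listed site were denser on the short scaffolds with at least 20 peaks than on long ones. On the 11 scaffolds of 7 Mb or more, a boundary set after seeing the values, there were 3.33 peaks with a site and 3.39 without one per Mb; on the 27 shorter scaffolds there were 3.42 and 8.33. The share with a site was 49.6% (46.5 to 52.7) and 29.1% (26.3 to 32.1). Over the 38 scaffolds the share rose with extent (rho = 0.563, r = 0.620; adjusted permutation p = 0.00045 and 9e-05; r = 0.602 without the 2 farthest; rho = 0.349 over the 53 scaffolds with at least 10 peaks), and the density of peaks without a site fell (rho = -0.720, r = -0.787; adjusted permutation p = 6e-05 and 3e-05; r = -0.780 without the 2 farthest). That of peaks with a site showed no relation that passed (rho = -0.0334, r = -0.100; adjusted permutation p = 0.842 and 0.556). NW_022279623.1 (4.30 Mb) was an exception, with 1.63 peaks without a site per Mb. Peaks without a site were also stronger on the shorter scaffolds, with a median of 5.93 (quartiles 3.49 and 10.8) against 3.50 (2.59 and 4.81) on the longer ones, while peaks with a site had medians of 8.06 and 7.38.

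The minimum of 20 peaks lets in short scaffolds only where they are dense, and may make part of this relation. Over all 50 scaffolds of at least 1 Mb, chosen by extent alone, rho was -0.484 for peaks without a site (bootstrap 95% interval -0.688 to -0.201, permutation p = 0.00054). For peaks with one it was 0.0395 (permutation p = 0.785). The first interval excludes 0 but reaches past the bound of -0.3. Pooled over the 39 of these scaffolds under 7 Mb, there were 3.28 peaks with a site and 8.13 without one per Mb, and 28.7% held a site. An extent read too short would raise both densities alike, but the rhos differed by -0.687 (-1.08 to -0.262), and by -0.523 (-0.913 to -0.0833) over the 50 scaffolds. Weak peaks near the threshold are argued against: in the stronger part of the list rho was -0.669 for peaks without a site (-0.813 to -0.417; permutation p = 1e-05, the smallest possible) and -0.437 (-0.668 to -0.139; permutation p = 0.00175) over the 50 scaffolds, where peaks without a site were stronger by 2.43 (1.95 to 2.94) on those under 7 Mb. Sites just short of the match threshold stay open, since the median site score had a rho of 0.256 with extent (-0.0868 to 0.533; permutation p = 0.121), with the bound at 0.3; no biological explanation was tested, and repeated sequence was not examined.

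Some strong peaks, a minority of the strongest, shared a paired arrangement of sites. Of 70 neighbouring sites within 200 bases of each other, 14 pairs lay exactly 11 bases apart, and the next commonest distance, 48 bases, had 4. The 14 pairs lay in 9 peaks on 5 scaffolds, and these 9 peaks had a median strength of 56.9 (14.98 to 169) and made up 5 of the 20 strongest peaks. The pairs were of only 2 kinds, ATACAATGTTTC overlapping TCAACATTGTTA (8 pairs) or TCAACATTGTAA (6 pairs), while the 56 pairs at other distances were of 51 kinds. Copies of the pair recurred 348 to 352 bases apart, which is consistent with copies of 1 repeated sequence. Whether several sites in a peak by themselves give a stronger peak cannot be told apart from this. Other peaks with 2 or more sites had a median strength of 10.4, a difference of 46.5, but the pairs were noticed because their peaks were strong. If they are copies of 1 sequence, they are also not separate cases. Whether reads of further copies were counted at these places was not examined.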
